A study of Homo sapiens with 12 samples.

How the data were processed

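The series holds RNA sequencing of U251-APP cells, a human glioblastoma line of astrocytic origin that stably carries a mutant form of the amyloid precursor protein, APP. Per the labels' protocols, Cas9 and a pair of guide RNAs flanking the target removed a binding site of the insulator protein CTCF, either the site called CTCF-A or the site called CTCF-B, after which single-cell clones were picked and the target region was sequenced. The labels give no coordinates for either site and do not state that the wild-type cells went through single-cell cloning. Each of the 3 groups (wild type, CTCF-A KO and CTCF-B KO) has 4 libraries of total RNA, sequenced as read pairs. The labels do not say whether the replicates of a group are separate clones or separate cultures, so the p-values measure only the spread between these samples, which may be technical.

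The submitters' processing notes name Trimmomatic 0.33 for trimming, featureCounts for counting, DESeq2 for the expression analysis, and the genome build GRCh38.p7. They do not give the aligner, the gene annotation used for counting, the strand setting, or the filter behind the 11178 genes listed. The deposited values are normalized expression values that the authors had already put on a log2 scale, as the values themselves show: they are fractional, run from 1.34 to 17.97, and give sums of the size of a sequencing library when 2 is raised to them. Which transformation gave the log2 values is not recorded. Whole reads could not be recovered from them, so the sequencing depth of each library is unknown and no counting interval can be given. Genes that share sequence with paralogs, such as the HLA class I genes, the AKR1C family, the protocadherin clusters and the metallothioneins, may have had reads split between copies. Reads of overlapping genes on opposite strands may likewise be mixed.

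The plan made before the data were examined took the table to hold linear values and called for log2(value + 1). Because the deposited values were log2 values already, they were used as they stood, without a pseudocount or further scaling. A gene was kept when its value, back on the linear scale, was at least 10 in at least 4 of the 12 libraries, which left 11128 genes and removed 50. One linear model of the 3 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with a trended empirical Bayes variance, and each contrast was tested two-sided with Benjamini-Hochberg adjustment at 0.05. The fold changes are differences of group means on the log2 scale, printed with the standard error from that model and 4 libraries per group. Positions and symbols refer to GRCh38, from GENCODE release 29, in which 11151 of the 11178 identifiers were found.

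The choices made before the data were examined were the model, the filter, the thresholds, 26 gene lists, the rule for named genes and the alternatives, apart from those listed here as added later. Under the rule, a gene is named in a comparison with wild type when its adjusted p is under 0.05, its absolute log2 fold change is at least 1, its mean is at least 50 on the linear scale in either group and all 4 knockout libraries lie on one side of all 4 wild-type libraries. Of these the 8 largest rises and the 8 largest falls were taken. Every kept gene of the 11p11.2 list, APP, and up to 4 members of each other list with the smallest adjusted p were added. For the comparison of the knockouts the 5 largest changes in each direction were taken, and for shared changes the 5 per direction with the largest smaller change. The 11p11.2 list was fixed because a label of the CTCF-B KO samples names MTCH2, a gene of that band. Lists with at least 5 kept genes were tested with camera from limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 21 lists tested, and again with an estimated correlation. The estimate came from all 12 libraries, so a list had the same value in each comparison. The 5 lists with fewer kept genes had no test: microglia and macrophage with 0 genes, mitochondrial mRNAs with 0, endothelial with 1, and epithelial and oligodendrocyte lineage with 2 each.

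A trend of the values with gene GC content and transcript length was estimated in each library from its deviation from the wild-type mean, with natural splines of 5 degrees of freedom for GC content, 4 for log2 length, and their product. These properties were known for 99.7% of the genes tested. Removing the trend was added as an alternative after the data had been seen, as were the same with the replicate number as a block, the use of CTCF-A KO replicate 4 as the only CTCF-A KO library, the 5 lists described under other observations, and the chromosome windows. For the windows, genes were grouped by 10 Mb of chromosome, keeping windows with at least 10 genes. A window was called shifted when, after removal of the trend, the median of every second gene differed from wild type by at least 0.2 on the log2 scale in the same direction in all 4 libraries. The remaining genes of the window were held out to measure the shift. The alternatives planned were pseudocounts of 0.25 and 10, no filter and a filter of 100, TMM-type, upper-quartile and quantile rescaling, a replicate block, a fit of only the 8 libraries compared, no variance trend, a test against a fold of 1.5, an estimated correlation in the list tests, a split of the wild-type libraries, and leaving out each library. Fits that need whole reads could not be run.

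The procedure was tested on simulated data. The simulations of the GC trend and of the windows were made after the data had been seen, since those steps were added then. For the comparison of CTCF-A KO with wild type, 200 of 11128 genes were changed by known amounts, 50 at each size. The fit recovered 68.0% of genes changed by a fold of 1.2, 96.0% at a fold of 1.5, and 100% at folds of 2 and 4, with 3 calls among 10928 unchanged genes. The simulated spread was that of wild type and CTCF-B KO, which is narrower than in CTCF-A KO. Recovery in the real CTCF-A KO libraries may therefore be lower. A GC trend placed in 3 of the CTCF-A KO libraries, replicates 1 to 3 as in the real data, with no gene changed, gave 5004 calls, and 0 after the trend was removed. That trend was linear in GC content, a shape the splines can follow, so other shapes were not tested. All 10 simulated shifted windows were found, with 0 others. This result holds only for the size of shift that was simulated. Recovery of windows with smaller shifts, near the cut used to call them, was not tested. Figures were drawn with matplotlib 3.10.9.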

Results

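Expression of 11128 genes was compared among 3 groups of U251-APP cells with 4 libraries each: wild-type cells, cells lacking the CTCF-binding site CTCF-A, and cells lacking the site CTCF-B. CTCF is a DNA-binding protein that shapes chromatin loops, and the series asks how gene expression differs once either binding site is gone. The number of reads behind each library is unknown. Libraries of one group were close to each other in wild type and CTCF-B KO, where the median absolute difference between replicates was 0.05 to 0.08 on the log2 scale. In CTCF-A KO it was 0.08 to 0.29.

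A deleted binding site is not a gene, so a table of genes cannot show the deletion itself. MTCH2, a mitochondrial outer membrane carrier named in a label of the CTCF-B KO samples (ENSG00000109919, chromosome 11, 47617315 to 47642623, GRCh38), was at 11.35 ± 0.03 in wild type and 11.34 ± 0.03 in CTCF-B KO (log2, mean ± SD, n = 4), a difference of -0.01 with an adjusted p of 0.945. In CTCF-A KO it was at 10.89 ± 0.14 and had fallen by 0.46. The mRNA of CTCF itself fell by 0.30 ± 0.04 (SE) in CTCF-A KO and by 0.26 ± 0.04 in CTCF-B KO. CTCF lies on 16q, between 60 and 70 Mb, where genes were somewhat lower in both knockouts. The 67 genes of that window had a median of -0.09 in CTCF-A KO and -0.08 in CTCF-B KO. With the GC and length trend removed these medians were -0.14 and -0.07.

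APP mRNA was lower in both knockouts (ENSG00000142192, chromosome 21, 25880550 to 26171128). It stood at 17.19 ± 0.04 (log2, mean ± SD, n = 4) in wild type, where it ranked 3 from the top in each library, at 15.79 ± 0.04 in CTCF-A KO and at 16.53 ± 0.03 in CTCF-B KO. The fall was to 0.379 of the wild-type level in CTCF-A KO and to 0.634 in CTCF-B KO (adjusted p 6.62e-12 and 5.23e-09). The table does not separate the introduced mutant APP from the cells' own gene.

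**Figure D1:**
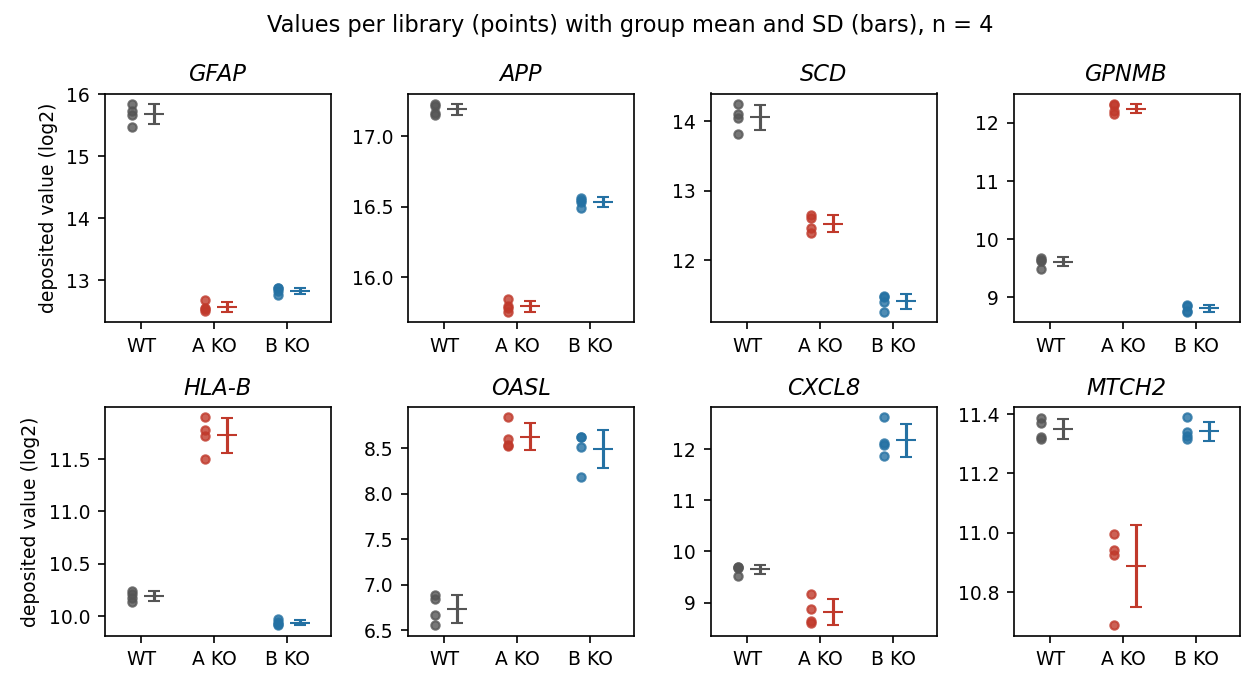
Deposited log2 values of 8 genes, with a panel per gene and its own axis: points are the 4 libraries of wild type (WT), CTCF-A KO (A KO) and CTCF-B KO (B KO), and bars are the group mean and SD. GFAP, APP and SCD are lower in both knockouts, OASL is higher in both, GPNMB and HLA-B are higher in CTCF-A KO alone, and CXCL8 is lower in CTCF-A KO and higher in CTCF-B KO.

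Loss of CTCF-A was accompanied by higher expression of antigen presentation, interferon, lysosome and antioxidant genes, and by lower expression of astrocyte and sterol genes, although with an estimated correlation the calls of these 6 lists were lost (lowest adjusted p = 0.174). GPNMB, a glycoprotein of lysosomes and melanosomes, rose the most of the genes named, 6.21-fold (log2 2.64 ± 0.05, SE, n = 4). GFAP, the intermediate filament of astrocytes, fell the most, to 0.116 of wild type (log2 -3.11 ± 0.07). In all, 7002 genes passed the test, 3540 higher and 3462 lower, of which 105 rose and 143 fell by at least 2-fold. Without CTCF-A KO replicate 4 these numbers were 120 and 276.

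The other large rises were AKR1C3 (2.21 ± 0.09), an aldo-keto reductase, OAS1 (2.16 ± 0.24) and OASL (1.89 ± 0.11), both induced by interferon, DHRS3 (2.10 ± 0.07) and CYP26B1 (1.91 ± 0.09), enzymes of retinoid metabolism, TSPAN10 (2.09 ± 0.09), a tetraspanin, and HMOX1 (2.01 ± 0.10), the inducible heme oxygenase. The other large falls were the cannabinoid receptor CNR1 (-2.67 ± 0.11), the neuropeptide Y receptor NPY1R (-2.58 ± 0.12), the adhesion molecule CADM1 (-2.24 ± 0.05), ANKRD1 (-2.19 ± 0.10), SCUBE3 (-2.17 ± 0.11), the fatty acid desaturase FADS2 (-2.09 ± 0.10) and the membrane glycoprotein GPM6B (-1.92 ± 0.08).

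All 11 measured genes of the MHC list rose in CTCF-A KO (11 adjusted over the list alone), with a median of 1.05, among them HLA-B (1.54 ± 0.07), HLA-F (1.22 ± 0.08) and the peptide transporter genes TAP1 (1.61 ± 0.09) and TAP2 (0.86 ± 0.05). Camera called the list (adjusted p 7.24e-08), but not with an estimated correlation (adjusted p = 0.28). Of 31 interferon response genes, 23 rose and 2 fell (25 changed adjusted over the list alone), including GBP1 (1.28 ± 0.08) and PSMB8 (1.31 ± 0.09). That list was called too (adjusted p 4.77e-07, and 0.316 with an estimated correlation).

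Of 30 lysosome and autophagy genes, 25 rose and 2 fell in CTCF-A KO (27 changed adjusted over the list alone). The cathepsins CTSD (1.65 ± 0.08) and CTSB (0.97 ± 0.06) and the autophagy receptor SQSTM1 (1.40 ± 0.07) rose, whereas MAP1LC3B (-0.75 ± 0.04), which lies in a stretch of 16q described further on, fell. Among 18 genes induced by the antioxidant regulator NRF2, 16 rose and 0 fell (16 adjusted over the list alone), including GSR (0.61 ± 0.04) and NQO1 (0.71 ± 0.07). Both lists were called (adjusted p 4.77e-07 for the lysosome list and 3.44e-06 for the NRF2 list), and neither with an estimated correlation (adjusted p = 0.28 for each).

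Astrocyte and glioma genes fell in 8 of 12 cases and rose in 0 (9 changed adjusted over the list alone). GFAP, the fatty acid-binding protein FABP7 (to 0.361 of wild type), the gap junction gene GJA1 (-1.15 ± 0.08) and SOX2 (-0.31 ± 0.04) were among them. The adjusted p was 1.44e-04, and 0.174 with an estimated correlation. Of 24 cholesterol synthesis genes 17 fell and 1 rose (19 changed adjusted over the list alone), with INSIG1 (-1.12 ± 0.06) and MSMO1 (-0.55 ± 0.05) among those lower. The adjusted p was 1.18e-04, and 0.28 with an estimated correlation.

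Genes of 11p11.2 fell together in CTCF-A KO: 18 of 26 were lower and 0 higher (19 changed adjusted over the list alone), with a median of -0.26 (adjusted p 1.13e-04, and 0.28 with an estimated correlation). CKAP5 (-0.96 ± 0.17), NUP160 (-0.71 ± 0.13), FNBP4 (-0.58 ± 0.10), PTPRJ (-0.55 ± 0.07), NR1H3 (-0.48 ± 0.12), MTCH2 (-0.46 ± 0.06), PACSIN3 (-0.44 ± 0.08) and PTPMT1 (-0.40 ± 0.12) fell most. DDB2, CELF1, HARBI1, ATG13, MDK, ARHGAP1, SLC39A13, DGKZ, MADD and ARFGAP2 fell by smaller amounts, down to 0.18, with MDK and ARFGAP2 losing their call when single libraries were left out. The 8 genes that did not pass were PSMC3 (-0.16), NDUFS3 (-0.18), KBTBD4 (-0.17), AMBRA1 (-0.06), C11orf49 (-0.08), ZNF408 (-0.02), ACP2 (0.01) and LRP4 (0.09). With the GC and length trend removed, 25 of the 26 passed as lower, with a median of -0.43.

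**Figure D2:**
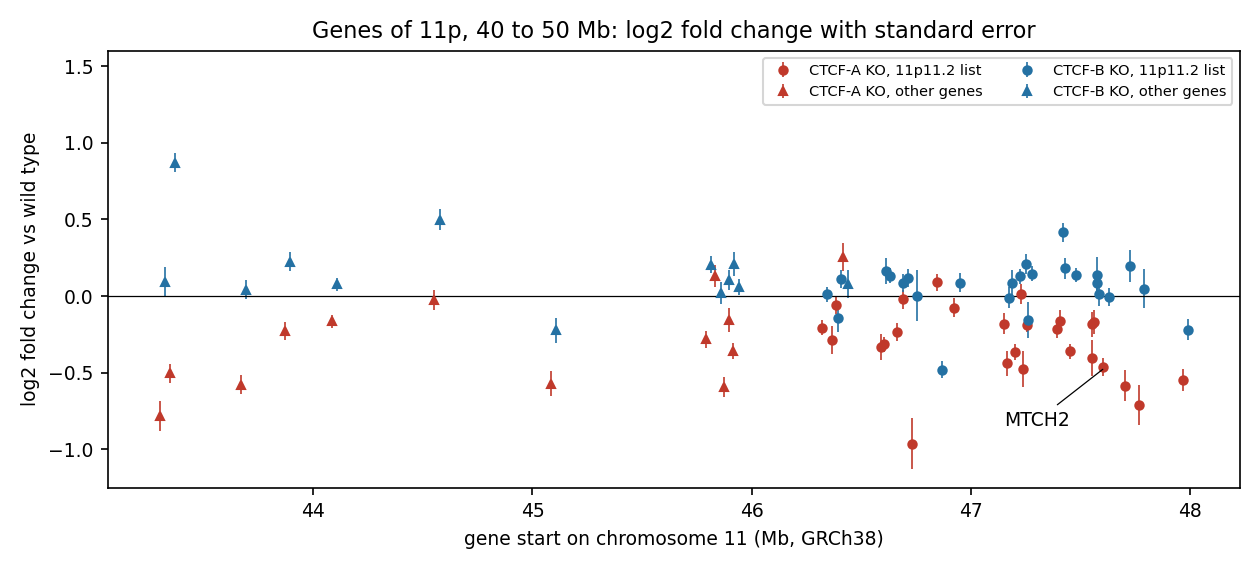
Log2 fold change against wild type, with its standard error, of the genes between 40 and 50 Mb of chromosome 11, by gene start (Mb, GRCh38). Circles are the 26 listed 11p11.2 genes and triangles the 13 other genes. Most CTCF-A KO values lie below 0 on both sides of 46 Mb, and most CTCF-B KO values lie just above 0.

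The remaining lists called in CTCF-A KO included genes of the cohesin complex and its partners, 11 of 14 lower and 1 higher, among them PDS5A (-1.18 ± 0.23) and YY1 (-0.25 ± 0.04) (adjusted p 0.0125, and 0.355 with an estimated correlation). Proliferation genes fell in 14 of 35 cases and rose in 5, including CCND1 (-1.36 ± 0.08), MKI67 (-1.41 ± 0.11), GINS2 (-0.86 ± 0.06) and CCNA2 (-0.61 ± 0.06) (adjusted p 0.026, and 0.355 with an estimated correlation). Without CTCF-A KO replicate 4 the proliferation list was not called (adjusted p 0.11). Hypoxia and glycolysis genes rose in 19 of 30 cases and fell in 4, with ADM (1.42 ± 0.09), ENO2 (1.02 ± 0.07) and P4HA2 (0.74 ± 0.06) higher and BNIP3 (-0.85 ± 0.06) lower (adjusted p 0.00855, and 0.542 with an estimated correlation). Ribosomal protein genes rose in 51 of 75 cases and fell in 4 (adjusted p 1.12e-04), complex I genes in 20 of 36 with 2 lower (adjusted p 0.0125), and replication-dependent histone genes in 6 of 7 with 0 lower (adjusted p 0.018). With an estimated correlation these adjusted p were 0.604, 0.604 and 0.355. With CTCF-A KO replicate 4 as the only CTCF-A KO library, the ribosomal, complex I, histone and cohesin lists were not called, and the medians of the ribosomal and complex I lists were below 0.

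Members of the APP processing list went both ways in CTCF-A KO, 11 higher and 11 lower of 29 (adjusted p 0.863). The secretase genes moved apart, with BACE2 higher (0.68 ± 0.05) and BACE1 lower (-0.59 ± 0.05), and the receptor LRP1 was higher (0.81 ± 0.06). Alzheimer risk genes were higher in 6 and lower in 6 of 20 cases (adjusted p 0.536), but with the GC and length trend removed 13 were higher and 6 lower and the list was called (adjusted p 0.0349). With the trend in place, CTSH (1.33 ± 0.10), GRN (0.77 ± 0.06) and BIN1 (0.58 ± 0.06) were higher. Neither did the neuron (adjusted p 0.101), matrix (0.178), protocadherin (0.269), p53 (0.444), NF-kB (0.444) and stress response lists (0.585) pass. Among their members, FN1 (1.10 ± 0.05), ITGA5 (1.06 ± 0.05), CSF1 (1.58 ± 0.06), PHLDA3 (1.13 ± 0.07) and NEFL (0.52 ± 0.05) rose, and COL1A1 (-1.03 ± 0.05), IL11 (-1.63 ± 0.10) and VLDLR (-1.12 ± 0.05) fell. The neuron list was called with the trend removed (5 of 6 higher, adjusted p 0.00246), with replicate 4 as the only CTCF-A KO library (0.00493) and without replicate 1 (0.0469), and the matrix list with replicate 4 alone (0.0243).

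These comparisons rest on libraries that differ within the CTCF-A KO group. In replicates 1, 2 and 3 the genes of highest GC content lay above those of lowest GC content by 0.96, 0.45 and 0.66 relative to wild type, whereas the same difference was 0.07 in replicate 4, -0.14 to 0.09 in wild type and -0.10 to 0.03 in CTCF-B KO. With that trend removed, 6831 genes passed, of which 4896 were among the 7002 in the same direction and 75 had the opposite direction. All 248 genes past 2-fold kept their call and direction, but with the trend removed 191 genes were past 2-fold, 77 higher and 114 lower. Replicate 4 alone gave 4654 calls. With an estimated correlation camera called 0 of the 13 lists, although 2 of 21 had an unadjusted p under 0.05. The fry test called 19, but it asks whether listed genes change, not whether they change more than other genes. With 62.9% of all genes passing, its calls do not set a list apart. The stress response list had a median just below 0 and a mean and test above 0, and for the other lists of this comparison the count of changed genes adjusted over the list alone differed by at most 2 from that over all genes.

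**Figure D3:**
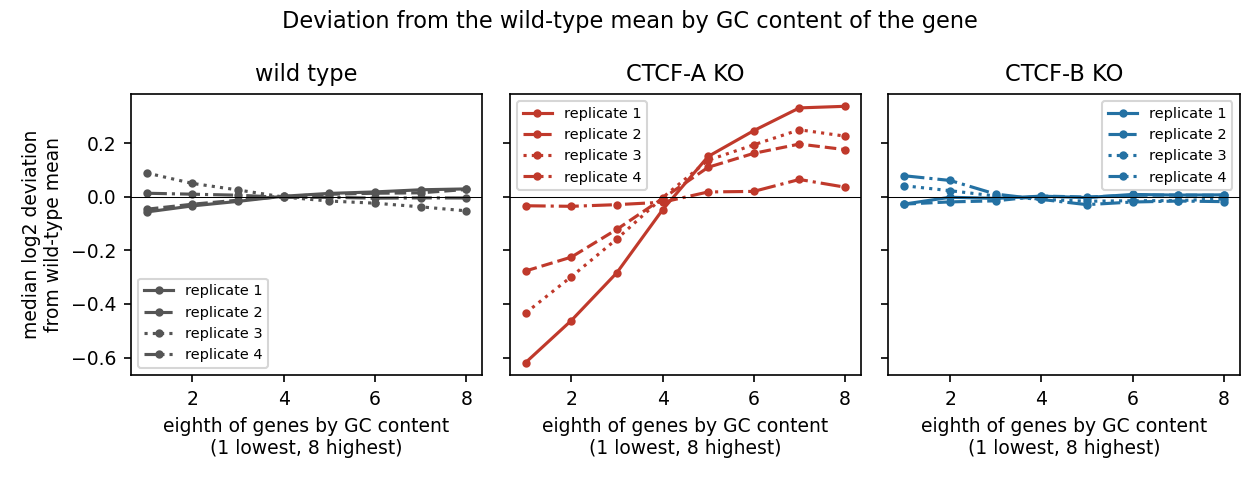
Median log2 deviation from the wild-type mean in 8 equal groups of genes ordered by GC content, a line per library, for each of the 3 groups. CTCF-A KO replicates 1 to 3 rise from the lowest to the highest GC content, while CTCF-A KO replicate 4, wild type and CTCF-B KO stay near 0.

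Loss of CTCF-B was accompanied by lower expression of sterol, astrocyte and matrix genes, and by higher expression of stress response and interferon genes. With an estimated correlation the sterol and astrocyte calls held, and those of the matrix (adjusted p = 0.187), stress response (0.332) and interferon lists (0.332) were lost. That correlation came from all 12 libraries with the GC and length trend in place, so it includes the spread within CTCF-A KO. It was not estimated for these lists with the trend removed. CXCL8, a neutrophil-attracting chemokine, rose 5.74-fold (log2 2.52 ± 0.15, SE, n = 4), and the stearoyl-CoA desaturase SCD fell to 0.159 of wild type (log2 -2.65 ± 0.09). In all, 4389 genes passed the test, 2100 higher and 2289 lower, of which 42 rose and 116 fell by at least 2-fold. A fit of only the 8 libraries compared, without the more variable CTCF-A KO libraries, gave 6601. With the GC and length trend removed 5880 passed, 4125 of them among the 4389 in the same direction.

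The other large rises were GDF15 (2.02 ± 0.09), a stress-induced cytokine, PTX3 (2.00 ± 0.08), a secreted pattern recognition protein, BEX2 (1.85 ± 0.08), NDRG1 (1.82 ± 0.13), TRIB3 (1.79 ± 0.08), a pseudokinase of the stress response, OASL (1.75 ± 0.11) and NUPR1 (1.71 ± 0.10). The other large falls were SCUBE3 (-3.32 ± 0.11), NPY1R (-3.07 ± 0.12), GFAP (-2.85 ± 0.07), the guidance cue NTN1 (-2.68 ± 0.10), ANKRD1 (-2.58 ± 0.10), the collagen COL14A1 (-2.52 ± 0.09) and the metallothionein MT1E (-2.39 ± 0.12).

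Cholesterol synthesis genes fell in 22 of 24 cases and rose in 0 (22 adjusted over the list alone), with a median of -0.54. INSIG1 (-1.69 ± 0.06) and LSS (-0.98 ± 0.06) were among those that fell. Astrocyte and glioma genes fell in 10 of 12 cases and rose in 0 (10 adjusted over the list alone), including the glutamate transporter SLC1A3 (-1.31 ± 0.08), PDGFRA (-1.49 ± 0.12) and SOX2 (-0.51 ± 0.04). Camera called both lists (adjusted p 4.19e-14 and 3.84e-06), also with an estimated correlation (adjusted p 0.02 and 0.0226). The fry test, which does not set a list against other genes, called 13 lists.

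In CTCF-B KO, 16 of 31 genes of the unfolded protein and integrated stress list rose and 7 fell (23 changed adjusted over the list alone), with SESN2 (1.54 ± 0.08), ATF3 (1.05 ± 0.08) and PPP1R15A (1.05 ± 0.08) higher beside TRIB3 (adjusted p 0.0017, and 0.332 with an estimated correlation). Interferon response genes rose in 18 of 31 cases and fell in 1 (21 changed adjusted over the list alone), among them IFIT2 (1.13 ± 0.13), IFIT3 (0.94 ± 0.14) and IFI44 (0.80 ± 0.12) (adjusted p 8.82e-06, and 0.332 with an estimated correlation). Matrix genes fell in 19 of 29 cases and rose in 4 (23 changed adjusted over the list alone), with COL5A1 (-1.22 ± 0.06), THBS1 (-1.12 ± 0.05) and TNC (-0.54 ± 0.03) lower and LOX (1.47 ± 0.07) higher (adjusted p 7.72e-04, and 0.187 with an estimated correlation).

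APP processing genes fell in 14 of 29 cases and rose in 2 in CTCF-B KO (16 changed adjusted over the list alone). The adaptor APBA2 (-2.15 ± 0.08) and the sorting receptor SORL1 (-1.34 ± 0.08) fell beside APP itself (adjusted p 7.72e-04, and 0.158 with an estimated correlation). Clustered protocadherins, whose promoter choice depends on CTCF, fell in 8 of 9 cases (8 adjusted over the list alone), including PCDHGA9 (-0.84 ± 0.10), PCDHB16 (-0.44 ± 0.06) and PCDHB10 (-0.43 ± 0.07) (adjusted p 5.50e-04, and 0.22 with an estimated correlation). Proliferation genes fell in 10 of 35 cases and rose in 2 (11 changed adjusted over the list alone), among them TYMS (-0.45 ± 0.05) and MCM6 (-0.52 ± 0.07) (adjusted p 0.0246, and 0.332 with an estimated correlation). The proliferation list was not called without wild-type replicate 3 (adjusted p 0.0572) or after quantile normalization (0.106), which also brought a call of the ribosomal list (adjusted p 0.00153, 32 higher and 5 lower).

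Genes of 11p11.2 were not called as a list in CTCF-B KO (adjusted p 0.195). SLC39A13 (0.42 ± 0.06), ACP2 (0.21 ± 0.06), MADD (0.15 ± 0.05) and CELF1 (0.14 ± 0.05) were higher, LRP4 (-0.48 ± 0.05) and PTPRJ (-0.22 ± 0.07) were lower, and the other 20, MTCH2 included, did not pass. Of the 13 unlisted genes between 40 and 50 Mb, 12 were higher by sign with the trend removed, with a median of 0.12. TTC17 (0.87 ± 0.06) and CD82 (0.50 ± 0.07) rose most among these 13. Leaving out single libraries ended the calls of ACP2, MADD, CELF1 and PTPRJ, as listed in the closing part on processing. The lysosome, NRF2, MHC, Alzheimer risk, neuron, cohesin, hypoxia, complex I, ribosomal, histone, p53 and NF-kB lists were not called, with adjusted p from 0.181 to 0.754. The neuron list had a mean below 0 and the lysosome list a median below 0, while their tests pointed up. Adjusted over the list alone, 14 p53 genes changed against 11 over all genes, and 6 ribosomal genes against 11. Single members still moved strongly, such as NEFL (-1.54 ± 0.05), a neurofilament gene, CCL2 (-1.28 ± 0.08), SLC2A1 (-0.79 ± 0.06), ABCA1 (-0.84 ± 0.13) and TAP2 (0.83 ± 0.05).

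Set against each other, the knockouts differed in 7349 genes, 3717 higher and 3632 lower in CTCF-A KO, with 226 and 137 past 2-fold. Without CTCF-A KO replicate 4 the latter were 257 and 276, so the larger number of rises does not hold there. GPNMB was 10.8-fold higher in CTCF-A KO (log2 3.44 ± 0.05, SE, n = 4), followed by the adhesion molecule L1CAM (3.05 ± 0.06), COL14A1 (2.87 ± 0.09), RPRM (2.86 ± 0.10) and METRN (2.68 ± 0.12). CXCL8 was lower in CTCF-A KO by a log2 difference of -3.35 ± 0.15, as were the cytokine IL11 (-2.09 ± 0.10), the transcription factors CREB5 (-1.92 ± 0.10) and ETV1 (-1.92 ± 0.13) and the phosphatase INPP5F (-1.87 ± 0.11). METRN and INPP5F lie in stretches of 16p and 10q in which neighbouring genes were shifted in CTCF-A KO. With the GC and length trend removed 7583 genes differed, 5559 of them among the 7349 in the same direction and 107 in the opposite one. Past 2-fold were then 152 genes higher and 120 lower in CTCF-A KO.

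Of the 21 lists, 13 differed between the knockouts. The MHC (10 of 11 genes), lysosome (24 of 30), protocadherin (9 of 9), matrix (19 of 29), cholesterol (15 of 24), NRF2 (13 of 18) and APP processing lists (16 of 29) were higher in CTCF-A KO, as were the interferon (15 of 31), ribosomal (47 of 75), complex I (22 of 36) and histone lists (5 of 7). The 11p11.2 list (22 of 26) and the stress response list (20 of 31) were lower. With an estimated correlation 0 of the 13 were called by camera (lowest adjusted p = 0.342), and 0 lists had an unadjusted p under 0.05. The fry test, which does not set a list against other genes, called 19. Without CTCF-A KO replicate 4 the interferon list (adjusted p 0.108) and the APP processing list (adjusted p 0.0705) did not differ, and the cohesin list did (0.0318). Quantile normalization ended the calls of the APP processing (0.108), matrix (0.108) and ribosomal lists (0.875). Replicate 4 as the only CTCF-A KO library ended those of the complex I (0.747), histone (0.0975) and ribosomal lists (0.382). The Alzheimer risk list differed with the trend removed (0.00857) and with replicate 4 alone (0.0315).

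Both knockouts shared some of their largest changes. GFAP, NPY1R, ANKRD1, SCUBE3 and CADM1 fell in both, and OASL, AKR1C3, NDRG1, ABLIM3 and the protocadherin PCDH10 rose in both. PCDH10 rose 2.30-fold in CTCF-A KO and 2.38-fold in CTCF-B KO, and ABLIM3 2.75-fold and 2.28-fold. By the rule for named genes 9 genes rose and 21 fell in both. That rule asks for groups of 4 that do not overlap, which chance gives in 2.86% of unchanged genes per comparison.

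Across the 11128 genes, 894 were higher and 823 lower in both knockouts, against 668 and 712 for independent lists of these sizes, and 1134 went opposite ways. With the GC and length trend removed, 1077 were higher and 1310 lower in both, against 827 and 981, so that shared falls outnumbered shared rises. The log2 fold changes had a Pearson r of 0.216 across genes, which are not independent replicates. Both comparisons use the same wild-type libraries, and unchanged groups simulated against them gave an r of 0.499. Their calls overlapped in 0 genes, but with no gene changed hardly any call is made. That overlap therefore cannot show what the shared libraries add to the observed one. The observed covariance was 0.0274 and the simulated one 0.00433. With the wild-type libraries split between the comparisons, r averaged 0.194 (0.118 to 0.263), with 528 shared rises against 379 for independent lists and 544 shared falls against 405.

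Neighbouring genes moved together along some chromosomes. In CTCF-A KO 25 of 278 windows of 10 Mb were shifted, 21 lower and 4 higher, and in CTCF-B KO 10 were, 7 lower and 3 higher, after removal of the GC and length trend. Over all their genes the 3 higher windows of CTCF-B KO had medians of 0.16, 0.12 and 0.14, below the 0.2 used to find them. That cut also passes over wider, smaller shifts. On 1q, all windows examined from 140 Mb on had medians from -0.22 to -0.15 in CTCF-B KO, but only that from 170 to 180 Mb was called. Between 150 and 160 Mb, for example, 122 of 142 genes were lower. The held-out genes moved with their window in 403 of 457 cases in CTCF-A KO and 104 of 121 in CTCF-B KO, whereas the values of single stretches given next cover all genes, those used to find the windows included. At the end of 10q, from 120 Mb on, 33 of 34 genes were lower in CTCF-A KO, with a median of -1.07 and library medians from -1.12 to -1.02. MKI67 and BNIP3 lie there. At the end of 16q, from 80 Mb on, 57 of 60 genes were lower, with a median of -0.68, among them GINS2 and MAP1LC3B, and at the start of 16p 121 of 133 were higher, with a median of 0.34, among them METRN, IL32, NDUFB10 and RPS2. In CTCF-B KO 71 of 78 genes between 40 and 50 Mb of 15q were lower, with a median of -0.32, B2M among them. Of the other genes named here, BACE1, CADM1 and SORL1 (11q), ANKRD1 and SCD (10q), PDS5A and CXCL8 (chromosome 4), APBA2 (15q) and VLDLR (9p) lie in windows that were lower in CTCF-A KO, with window medians from -0.39 to -0.22, and CCL2 (17q) in one that was higher (0.25). The windows of CTCF-A KO held 57 of its 143 falls and 8 of its 105 rises of at least 2-fold, and those of CTCF-B KO 4 of 116 falls and 1 of 42 rises. The windows of CTCF-A KO held 926 genes, with 10202 outside, and those of CTCF-B KO 249, with 10879 outside. Since the windows were found from the same values, most of them as lower, part of the excess of falls is built in.

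**Figure D4:**
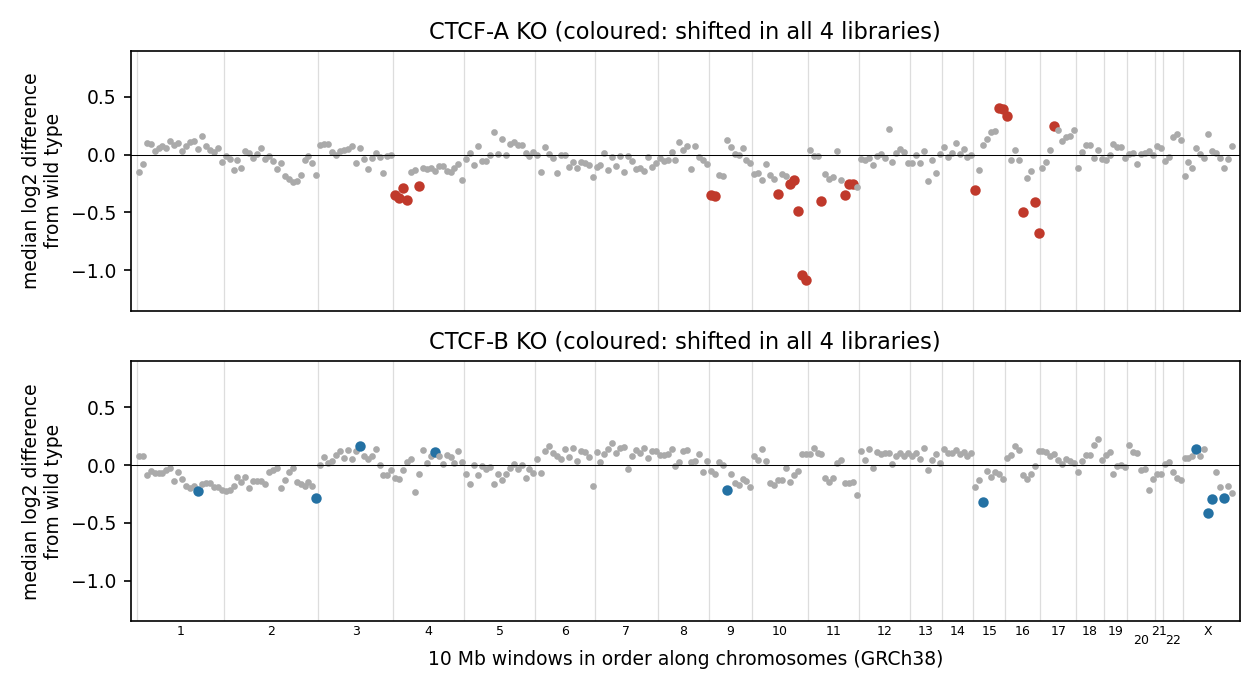
Median log2 difference from wild type, GC and length trend removed, in 278 windows of 10 Mb in order along chromosomes 1 to 22 and X. Each point is a window, and coloured points are those shifted in all 4 libraries, 25 in CTCF-A KO and 10 in CTCF-B KO. The lowest values, near -1.07, are at the end of chromosome 10 in CTCF-A KO.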

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

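All tests of explanations in this part were chosen after the result was seen.

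Grouping by chance was tested with the 35 splits of the 8 libraries of each comparison into 4 and 4. For CTCF-A KO against wild type 1 split, the real one, gave as many genes, with 7002 against 3349 in the highest other. That other split sets wild-type replicate 1 with CTCF-A KO replicates 1 to 3 against the rest and follows the GC trend, and with the trend removed the highest other was 0 against 6831. For CTCF-B KO against wild type 1 split gave as many, with 4389 against 1. For the comparison of the knockouts 1 split gave as many, with 7349 against 1781, the latter again with CTCF-A KO replicates 1 to 3 on one side. An exact p of 0.0286, for 1 split of 35, is the smallest this test can give, so it cannot exclude chance beyond that. The splits show that the groups differ, and whether other clones would differ likewise was not tested.

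The first pattern is the trend of CTCF-A KO replicates 1 to 3 with GC content and length, which explained 45.7%, 24.2% and 33.1% of the variance of their deviations and 1.49% in replicate 4. This share alone does not set those replicates apart, since it was 26.2% in wild-type replicate 3. The deviations were smaller there, with a median absolute deviation of 0.05 against 0.25 in CTCF-A KO replicate 2. GC and length bias as the whole cause of the changed genes is argued against by the 4896 calls that stayed in the same direction once the trend was removed. A mislabelled wild-type library as replicate 4 is argued against by 86.9% of 396 genes, chosen from replicates 1 to 3 alone, that lay outside the wild-type range in the same direction in replicate 4. An effect of the knockout on GC-rich genes cannot be told apart from a difference in library preparation, since only 1 library, with a high-minus-low difference of 0.07 (0.0694), lacks the trend and the labels give no batch.

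The second pattern is the set of neighbouring genes shifted together in chromosome windows. Chance placement is argued against, since 0 of 1000 shuffles of gene positions gave 25 windows in CTCF-A KO, the highest being 7. GC and length bias is argued against, since in windows found from replicates 1 to 3 the held-out genes moved the same way in replicate 4 in 84.0% of cases. A candidate explanation is a difference in chromosome copy number between the knockout clones and the wild-type cells, since 88.2% of 457 held-out genes of the shifted windows moved with their window. Regulation of whole stretches would give the same values and was not tested, and no DNA was measured.

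The third pattern is the fall of the 11p11.2 genes in CTCF-A KO, for which no biological explanation was tested, since the labels do not place the CTCF-A site. GC and length bias is argued against, since 25 of the 26 listed genes passed the test as lower with the trend removed. A change limited to the listed genes is argued against, since the 13 other genes between 40 and 50 Mb had a median of -0.37, and the listed genes differed from them by -0.06 (permutation test, 100000 resamples, two-sided p 0.333). A shift of the wider stretch of chromosome 11 may account for it, since 92.3% of those other genes, by sign alone, were lower, and whether a copy number change or the deletion underlies such a shift was not tested.

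Single libraries stood apart from the other 3 of their group in 22 of 567 groups examined, where chance gives about 1 in 20, or 28.35. The share of the group's range between that library and its nearest neighbour was 0.86 for OAS1 in CTCF-A KO (replicate 1 high). It was 0.867 for CXCL8 in wild type (replicate 2 low). It was 0.954 for NUPR1 in CTCF-B KO (replicate 4 low). For HARBI1 in wild type the share was 0.844 (replicate 4 low). For C11orf49 it was 0.928 in wild type (replicate 2 high) and 0.86 (0.8597) in CTCF-B KO (replicate 1 high). For FNBP4 in wild type it was 0.876 (replicate 3 high). FABP7 in CTCF-A KO gave 0.882 (0.8821, replicate 4 low). GAD1 in wild type gave 0.853 (replicate 3 low). CNP in CTCF-B KO gave 0.845 (replicate 3 low). MUC1 in wild type gave 0.91 (replicate 2 high). KRT18 in wild type gave 0.842 (replicate 3 low). GADD45A in CTCF-A KO gave 0.956 (replicate 4 low). TAP1 in CTCF-A KO gave 0.831 (replicate 1 high). GSR in CTCF-A KO gave 0.92 (replicate 4 low). IFIT2 in CTCF-A KO gave 0.882 (0.8824, replicate 4 high). IFI44 in wild type gave 0.976 (replicate 3 high). CCL2 in CTCF-B KO gave 0.834 (replicate 1 high). UHRF1 in wild type gave 0.897 (replicate 1 high). MCM2 in CTCF-B KO gave 0.855 (replicate 2 low). NPC1 in CTCF-B KO gave 0.935 (replicate 2 high). The median absolute deviation of a library from the wild-type mean gave 0.916 in CTCF-B KO (replicate 2 high). CTCF-A KO replicate 4 and wild-type replicate 3 each held 4 of the 22.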

How the results depend on the processing

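The alternatives that remove the GC and length trend, with or without a block, or use CTCF-A KO replicate 4 alone were chosen after seeing the data, and the other alternatives were fixed in advance. Most alternatives left the counts of genes within 1.5 times. A test against a fold of 1.5 gave 320 genes for CTCF-A KO, 229 for CTCF-B KO and 571 between the knockouts, since it asks for larger changes. Using only the 8 libraries compared gave 6601 genes for CTCF-B KO, since the wider spread of CTCF-A KO no longer entered the fit. For CTCF-A KO the same choice lowered the number from 7002 to 6144. CTCF-A KO replicate 4 alone, assumed to vary like the other groups, gave 4654 genes, 3694 of them among the 7002 in the same direction. With an estimated correlation camera called 0 of the 13 lists in CTCF-A KO and 2 of the 8 in CTCF-B KO. ACP2 in CTCF-A KO, 0.01 and not called, was -0.22 with the trend removed, -0.22 with a replicate block and the trend removed, and -0.16 with replicate 4 alone; the cause was not tested.

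Leaving out single libraries gave 6182 to 8210 genes for CTCF-A KO, 3670 to 3875 for CTCF-B KO and 6734 to 8425 between the knockouts, 12 to 14 and 7 to 8 lists, and an r of 0.194 to 0.238. Without CTCF-A KO replicate 4 the falls of at least 2-fold in CTCF-A KO went from 143 to 276. Among 254 results for named genes, 9 lost their call when some library was left out: ARFGAP2, PCDHB9 and MDK in CTCF-A KO, and PTPRJ, H2BC12, CELF1, MAZ, ACP2 and MADD in CTCF-B KO. The other alternatives fixed in advance, apart from the fold test, ended 5 calls (KRT18, ARFGAP2, PTPRJ, H2BC12 and CELF1) with 0 directions turned. The fold test ended 115. The added alternatives ended calls for 8, namely MYRF, NDUFS1, PCDHGC3, CNP, MUC1, PCDHB9 and H2BC5 in CTCF-A KO and RPS7 in CTCF-B KO. The replicate block gave 7060, 4414 and 7420 genes and 13 and 8 lists with 0 calls of named genes ended. The numbers did not pair the samples: same-numbered libraries correlated between -0.32 and 0.43, over 0.1 in 5 of 12 cases and best with their own number in 4. The planned fits of edgeR and DESeq2 were not run because reads could not be recovered, and the unknown depth leaves the precision of low values open.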

Other observations

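All lists and tests in this part were chosen after the values had been seen. Genes of fatty acid synthesis and desaturation fell in 12 of 15 cases in CTCF-A KO and in 9 of 15 in CTCF-B KO, with 3 and 2 higher. FADS2 (-2.09 and -1.70), SCD (-1.53 and -2.65), FASN (-0.40 and -1.08) and SREBF1 (-0.52 and -1.72) fell in CTCF-A KO and CTCF-B KO. Camera gave adjusted p of 0.00197 and 2.18e-05 over 5 lists (0.0384 and 0.00529 with an estimated correlation). Without FADS2 and SCD, which prompted the list, camera p was 0.0206 and 5.47e-04 (0.0367 and 0.00524 with an estimated correlation), with 10 and 7 of 13 lower. Genes of the retinoic acid response rose in 6 of 10 cases in CTCF-A KO, among them STRA6 (1.39 ± 0.08) beside DHRS3 and CYP26B1 (adjusted p 0.00197, and 0.0885 with an estimated correlation), and were not called in CTCF-B KO (adjusted p 0.484), where STRA6 fell by 1.19. Without DHRS3 and CYP26B1, which prompted the list, 4 of 8 genes rose in CTCF-A KO (camera p 0.0384, and 0.103 with an estimated correlation). The metallothionein list was not called in either knockout (camera adjusted p 0.106 and 0.795). Its 5 measured genes were MT2A, MT1E, MT1F, MT1X and the zinc transporter gene SLC30A1, which is not a metallothionein.

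The rise of GPNMB, TSPAN10, ACP5 (1.69 ± 0.10) and CTSD in CTCF-A KO prompted the hypothesis of a wider rise of targets of the lysosomal regulators MITF and TFE3. The list rose in 18 of 21 cases and fell in 1 (adjusted p 1.45e-06, and 0.0384 with an estimated correlation). Without these 4 genes and the members of the lysosome list, 9 genes were left, which were higher as a set with the trend removed (camera p 0.0233, and 0.0427 with an estimated correlation), 5 higher and 0 lower. They include the regulators MITF and TFE3 themselves, and MITF mRNA rose by 0.45 in CTCF-A KO and fell by 1.33 in CTCF-B KO. A rise of this list may reach beyond the genes that prompted it, although 9 genes are few and the activity of neither factor was measured.

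ETV1 and CCND1 were lower in CTCF-A KO than in CTCF-B KO, which prompted the hypothesis of an opposite change of feedback genes of the MAPK pathway. In CTCF-A KO 13 of 18 list members fell and 2 rose, including DUSP4 (-0.69 ± 0.07), SPRY4 (-0.45 ± 0.06) and ETV4 (-0.91 ± 0.07), and in CTCF-B KO 13 rose and 2 fell, with DUSP6 at 1.17, ETV5 at 1.08 and DUSP4 at 0.94. Without ETV1 and CCND1, and with the GC and length trend removed, the other 16 genes were lower in CTCF-A KO than in CTCF-B KO as a set, with 13 lower and 1 higher against 14 and 1 in the deposited values (camera p 3.15e-06, and 0.0668 with an estimated correlation). MAPK signalling may differ between the knockouts, a hypothesis that phosphorylated proteins would have to test.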
